A study of Homo sapiens with 2 samples.

How the data were processed

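Total RNA (200 ng per labelling) of HL-60 cells treated for 24 h was amplified and labelled with Cy3 or Cy5 and hybridised to 2 two-colour Agilent whole-genome expression arrays, per the labels' protocols. The array with ATRA in Cy5 is array 1 and that with ATRA and ATO in Cy5 is array 2, as the labels give the dyes. The arrays lay on the same slide and in the same scan per the file headers, so no slide or scan batch could be tested. Array and dye orientation cannot be told apart.

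Spots were read with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited scanner files give the intensity of each spot in each dye, the intensity around it, and flags of spot quality. They also hold the authors' processed log10 ratio of Cy5 over Cy3, after background subtraction and linear and LOWESS dye normalization per the file headers, with a p-value for each ratio per the file headers. The deposited value table equals that log10 ratio within rounding (largest difference 5.000e-06). Its scale is thus log10, its column medians are 0 and 0, and its direction is Cy5 over Cy3 without turning the swapped array. On spike-in RNA of known ratio the slope of observed on expected log ratios was 0.92 on each array per the file headers. Large ratios among the authors' processed values were thus slightly understated. The ratios used below were processed otherwise and were not checked on the spike-ins. With them 42 features were at least 2-fold higher on both arrays and 7 lower, against 98 and 16 with the authors' log ratios. On array 2 the headers mark the spread of the Cy5 negative control spots (7.37) as outside its range, against 5.33 on array 1.

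From the intensities, the background was corrected with normexp at an offset of 50, which shrinks the ratios of dim spots, and each array was normalized by loess with control spots at weight 0. Each log2 ratio was turned so that positive means higher with ATO. Of 44495 spots on each array, 1377 control spots were left out, as were spots flagged as outliers, and the spots of a probe were averaged. A probe was tested if it was well above background on both arrays in the channel of at least one treatment, which 17578 of 34127 probes were; 1 probe was dropped for outlier flags. Probes were named through the RefSeq table given with the data: 24910 by RefSeq accession and 2256 by symbol or synonym, while 470 kept the name in the file and 6491 had no symbol. No coordinates are printed, because the array's annotation is on another genome build than that table. For each gene the tested probe with the highest mean intensity was used. Of 2891 genes with more than 1 tested probe, CES1, TRMT2B and TUT4 had probes that differed by 1 or more on the log2 scale.

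Features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. With 2 arrays there is 1 residual degree of freedom, to which the pooled estimate added 21.9. The dye effect cancels in the mean and stays in the spread. Gene lists were tested two-sided with camera at a preset correlation of 0.01, adjusted over 22 lists, and again with an estimated correlation, which rests on 1 residual degree of freedom. With the preset correlation 10 lists shifted up and 2 down, and none passed with the estimated one. Even the NRF2 list, at p = 1.921e-28 with the preset correlation, had an unadjusted p of 0.05 with the estimated one. On 1 residual degree of freedom that test could hardly pass any list after adjustment. Its adjusted p-values below therefore speak neither for nor against a shift. Errors are the SD of the 2 arrays. The number of arrays limits the precision. Bounds compare the mean normalized log2 level in the brighter treatment with, on each array, the higher of the dim probe's own level and the lowest level among probes well above background (each channel after loess and Aquantile). Bounds of 1-fold or more were found for 90 genes higher and 19 lower with ATO, and 31 of them passed the test.

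The functions were tested on simulated arrays with the intensities of these probes, in which 200 of 14076 genes were changed and a list of 25 others was shifted by a log2 ratio of 0.5. For the comparison of ATRA with ATO against ATRA, 100% of the 66 genes changed by a log2 ratio of 2, 100% of the 66 changed by 1 and 76.5% of the 68 changed by 0.5 were called. The 209 calls were 184 of the changed genes, 21 members of the shifted list and 4 false calls. The median estimate was 0.98, 0.92 and 0.86 of the true log2 ratio. The simulated median SD of the arrays was 0.10, as in the data, but the simulated variances differed less between genes (prior degrees of freedom 1198, against 21.9), so these shares may be too high for the real arrays.

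The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Exceptions are the tests under other observations and the alternatives said below to be chosen after the data were seen. Named genes are the 12 largest changes in each direction among called genes with the same direction and a log2 ratio of at least 0.58 in size on each array, and HMOX1, TXNRD1, MT2A, AQP9, CD38, ITGAM, CYP26A1, MYC, CDKN1A and PML in any case. They also include up to 4 called members of each list with the largest change (or 2 where none was called) and the 3 largest bounds in each direction. A few genes that this rule takes from the lists are not reported here. Alternatives were another normexp offset, no background correction, the authors' log ratios, median centring, other filters on dim probes, other ways to combine probes, other variance models and each array alone.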

Results

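HL-60 is an established human myeloid leukaemia line that can mature along the neutrophil lineage. Cells were treated for 24 h with 0.1 µM all-trans retinoic acid (ATRA) or with 0.1 µM ATRA and 0.5 µM arsenic trioxide (ATO). ATRA is a ligand of the retinoic acid receptors, and ATO is an arsenical used with it against acute promyelocytic leukaemia. The comparison asked which transcripts differ when ATO is added to ATRA. Messenger RNA was measured on 2 two-colour Agilent arrays that held both treatments on each array, with the dyes swapped. Array 1 carried ATRA in Cy5 and ATRA with ATO in Cy3, and array 2 the reverse. No untreated cells and no cells with ATO alone were analysed here, so each value is the difference that ATO made on top of ATRA. The labels do not say whether the arrays carry separate cultures or the same extracts, so the p-values measure only the spread between these arrays, which may be technical. In the channels, 53.9% to 55.8% of the non-control spots were well above background, and no spot was saturated. After the ratios were turned to the same direction, the 14076 tested features (12006 genes with a symbol and 2070 transcripts without) gave a Pearson r of 0.51 and a Spearman rho of 0.33 between the arrays. That correlation is across genes, which are not independent replicates.

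HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, showed the largest increase with ATO, at 9.87-fold (log2 3.30 ± 0.12, SD, n = 2 arrays; limma adjusted p = 4.472e-16); with the authors' log ratios it was 17.7-fold (adjusted p = 7.255e-07). PIR, an iron-binding nuclear protein, rose 4.72-fold (log2 2.24 ± 0.22). FTH1, the ferritin heavy chain, rose 3.71-fold (log2 1.89 ± 0.19). The largest decrease was in PRTN3, a serine protease of neutrophil primary granules, which was 5.49-fold lower (log2 -2.46 ± 0.28; adjusted p = 5.786e-13). In all, 599 features were higher and 297 lower with ATO, which is 6.37% of those tested. Most changes were small, with a median log2 ratio of 0.49 among the higher and -0.45 among the lower features. At least 2-fold on each array, 42 features were higher and 7 lower, and limma called all 49 of them. On single arrays, 54 and 64 features were at least 2-fold higher and 11 and 29 lower. The counts depend on the intensity-dependent dye correction: with median centring in place of loess, 29 features were higher and 3 lower, and of the 79 called genes chosen for naming 20 kept the call. In 18 features the log2 ratio was 1 or more in size on array 2 and under 0.3 on array 1, and 15 of these 18 are among the calls.

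**Figure D1:**
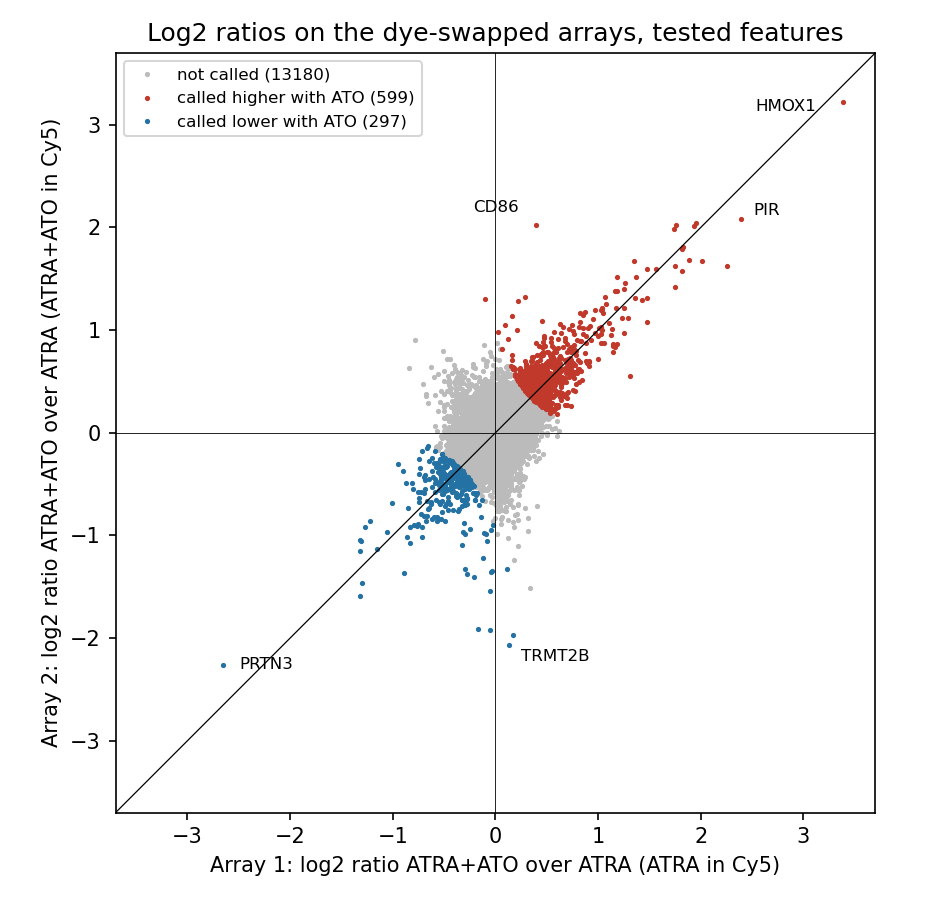
Each point is a tested feature, with the log2 ratio of ATRA with ATO over ATRA on array 1 on the horizontal axis and on array 2 on the vertical axis; red points are the 599 features called higher, blue points the 297 called lower, and the line marks equal ratios. HMOX1 and PRTN3 lie at the ends of the line, while TRMT2B, at 0.13 on array 1 and -2.06 on array 2, lies far from it.

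Among the other genes with the largest increases were GPAT3, an enzyme of glycerolipid synthesis, at 3.99-fold, and AIM2, a sensor of cytosolic DNA, at 3.83-fold. GDF15, a stress-responsive cytokine, rose 3.59-fold, and AKR1C3, an aldo-keto reductase, rose 3.49-fold. LAMB3, a laminin chain, rose 3.23-fold. CES1, a carboxylesterase, rose 3.54-fold by its brightest probe, but its other tested probe had a log2 ratio of 0.02 and the mean of its probes was 0.92. With the authors' log ratios the brightest probe of CES1 gave 6.08-fold. The probe for the ferritin pseudogene FTH1P20 rose 3.94-fold, and since the sequence is nearly that of FTH1 the signal is uncertain. Among the decreases, the probes for the class I histocompatibility genes HLA-B, HLA-C, HLA-F and the pseudogene HLA-J were 2.60-fold, 2.21-fold, 2.13-fold and 2.06-fold lower. These genes are near-identical in sequence, so which of them fell is uncertain. PLPPR3 was 2.19-fold lower, MZB1 2.01-fold lower and the long non-coding RNA MIR503HG 1.83-fold lower. TET1, an enzyme that oxidises 5-methylcytosine, was 1.93-fold lower by its brightest probe, while its other probe stood at a log2 ratio of -0.07.

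**Figure D2:**
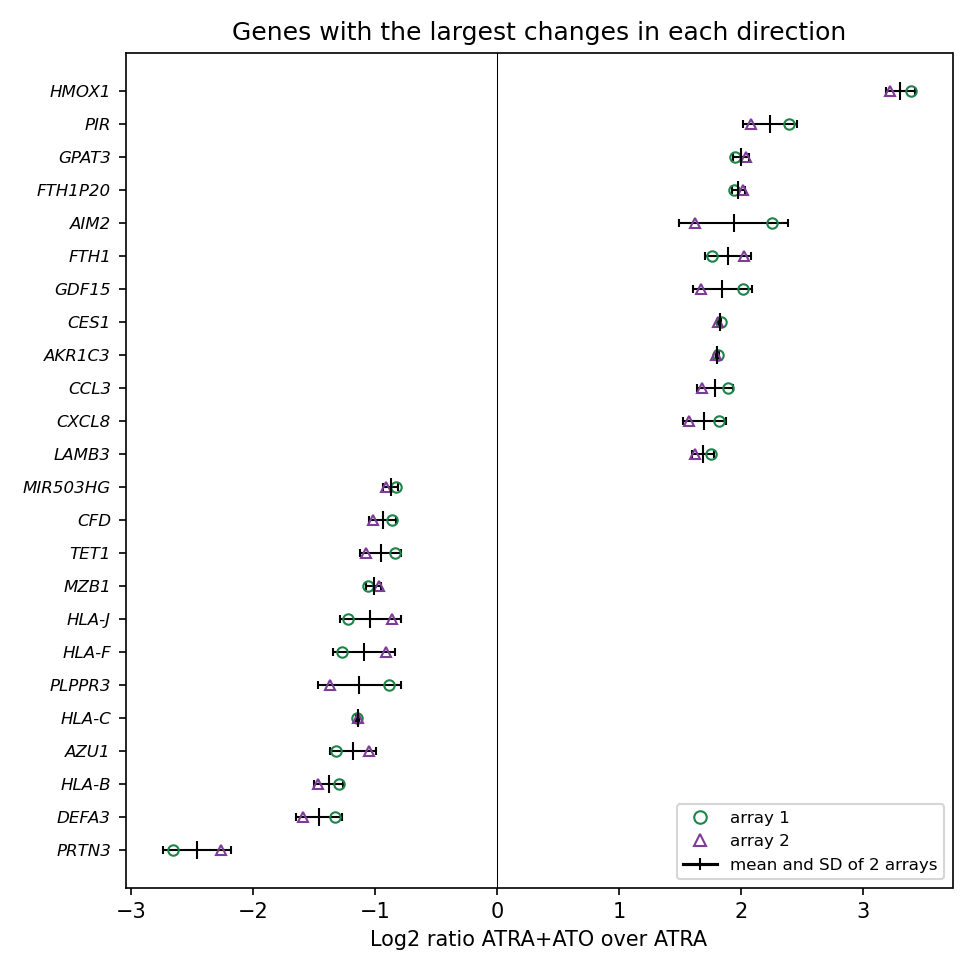
The horizontal axis gives the log2 ratio of ATRA with ATO over ATRA for the 12 genes with the largest increase and the 12 with the largest decrease among those called with a log2 ratio of at least 0.58 in size on each array; circles are array 1, triangles array 2, and black marks the mean and SD of 2 arrays. HMOX1 stands apart at 3.30 and PRTN3 at -2.46.

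Genes of the NRF2 response, the antioxidant programme of the cell, rose as a group. Of 24 measured members, 14 were higher, none was lower and 10 did not pass the test; 20 were higher when adjusted over the list alone. The median log2 ratio was 0.46, and the group shift passed camera with a preset correlation (adjusted p = 4.225e-27) but not with an estimated one (adjusted p = 0.36). Beside HMOX1, PIR and FTH1, the cystine transporter gene SLC7A11 rose 2.90-fold (log2 1.53 ± 0.08, SD, n = 2). TXNRD1, which encodes thioredoxin reductase 1, rose 1.37-fold (log2 0.45 ± 0.07; adjusted p = 0.00846).

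Metallothioneins, the metal-binding proteins, did not show such a shift. None of the 11 measured members of that list passed, over all genes or adjusted over the list alone. MT2A had a log2 ratio of 0.07 ± 0.05 (adjusted p = 0.82), MT1M -0.31 ± 0.18 and the zinc exporter SLC30A1 0.23 ± 0.10. Of 16 heat shock genes, HSPA1L alone was higher, at 1.47-fold, and the list did not shift (adjusted p = 0.38; 2 higher when adjusted over the list alone). Of 20 genes of the ATF4 integrated stress response, TRIB3 rose 1.35-fold, PPP1R15A rose 1.34-fold and DDIT4 fell by 0.62 on the log2 scale, with the same 2 higher and 1 lower when adjusted over the list alone and no list shift (adjusted p = 0.58). With the authors' log ratios TRIB3 and PPP1R15A lost the call (adjusted p = 0.11 and 0.06), as they did without background correction (adjusted p = 0.07 and 0.06). Endoplasmic reticulum chaperone genes shifted down, with a median log2 ratio of -0.18 over 18 members (adjusted p = 0.00547; adjusted p = 0.42 with an estimated correlation). The list median was -0.09 on array 1 and -0.22 on array 2. HSP90B1 alone passed there, at 1.29-fold lower, but lost the call with the authors' log ratios (adjusted p = 0.16), without background correction (adjusted p = 0.10) and with a normexp offset of 10 (adjusted p = 0.08). HSP90B1 also lost it with both other filters on dim probes (adjusted p = 0.06 for each). On the chaperone list 2 members were lower when adjusted over the list alone. Of 9 genes of arsenic transport and metabolism, the glutathione transferase gene GSTP1 was higher, at 1.30-fold, also when adjusted over the list alone. The GSTP1 call was lost with the authors' log ratios (adjusted p = 0.16), without background correction (adjusted p = 0.09) and with a normexp offset of 10 (adjusted p = 0.07). The arsenic list did not shift (adjusted p = 0.75), and its median of -0.06 and mean of 0.03 differed in sign. On single arrays the median was 0.13 on array 1 and -0.02 on array 2. AQP9, an aquaglyceroporin that carries arsenite, was not well above background on both arrays in either treatment.

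Most measured genes of neutrophil maturation were higher with ATO, while most primary granule and promyelocyte genes were lower. Of 21 measured maturation genes, 13 were higher and none lower, also when adjusted over the list alone, with a median log2 ratio of 0.54 (adjusted p = 8.512e-20; adjusted p = 0.36 with an estimated correlation). The formyl peptide receptor gene FPR1 rose 2.04-fold, S100A8 2.04-fold and ITGAX 1.97-fold. ITGAM, which encodes the surface marker CD11b, rose 1.62-fold (log2 0.70 ± 0.32; adjusted p = 2.527e-04). The 8 tested maturation genes that did not pass ranged from a log2 ratio of -0.001 (ALPL) to 0.21 (CYBA). The list held 31 genes, and those not tested included LTF, LCN2, CAMP, MMP8 and CEACAM8, so the shift covers only part of the list. Of 18 primary granule and promyelocyte genes, 10 were lower and 1 higher (12 lower and 1 higher when adjusted over the list alone), with a median of -0.36 (adjusted p = 9.695e-14; adjusted p = 0.36 with an estimated correlation). Beside PRTN3, DEFA3 was 2.75-fold lower, AZU1 2.27-fold lower and CFD 1.92-fold lower. DEFA3 is nearly identical to DEFA1, so its value may hold both. BPI, a bactericidal granule protein, was the member that was higher, with a log2 ratio of 0.48, and is named after its value was seen.

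Retinoic acid target genes were higher with ATO than with ATRA alone in 9 of 15 measured members, also when adjusted over the list alone, and none was lower. Their median log2 ratio was 0.38 (adjusted p = 1.267e-10; adjusted p = 0.36 with an estimated correlation). ICAM1 rose 2.30-fold, ASB2 1.998-fold and TGM2, a transglutaminase, 1.70-fold. TNFAIP2 rose too, with log2 ratios of 0.86 and 1.14 on the arrays. The 6 members that did not pass, named after their values were seen, were CEBPE at 0.18, HIC1 at 0.13, PRAM1 at 0.09, RARG at 0.02, RARA at 0.003 and CRABP2 at -0.13. Whether retinoid signalling itself rose was not tested. CD38, a surface enzyme used as an early marker of ATRA response, rose 1.29-fold (log2 0.37 ± 0.006; adjusted p = 0.04). The CD38 call was lost with a normexp offset of 10 (adjusted p = 0.07), without background correction (adjusted p = 0.08) and with the authors' log ratios (adjusted p = 0.12). CYP26A1, the retinoic acid hydroxylase, was not well above background on both arrays in either treatment. PML, which forms nuclear bodies that arsenic targets, had a log2 ratio of -0.07 ± 0.09 and did not pass (adjusted p = 0.83).

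Inflammatory cytokine and NF-κB target genes had the highest median of the lists, at a log2 ratio of 0.72 over 17 measured members, of which 13 were higher and 1 lower, also when adjusted over the list alone. The shift had an adjusted p of 3.649e-23, and an adjusted p of 0.36 with an estimated correlation. CCL3 rose 3.45-fold, CXCL8 3.24-fold, CCL4 3.00-fold and IL1B 2.63-fold. The CCL3 and CCL4 probes may also read the near-identical CCL3L and CCL4L genes. SOD2, the mitochondrial superoxide dismutase, was the lower member, at -0.47 on the log2 scale, and is named after its value was seen. Monocyte and macrophage markers were higher in 7 of 12 members, also when adjusted over the list alone, with a median of 0.46 (adjusted p = 1.739e-06; adjusted p = 0.37 with an estimated correlation). EGR2 rose 2.18-fold, CTSL 1.58-fold and CSF1R 1.47-fold. CD86 was called at 2.32-fold, but its log2 ratio was 0.40 on array 1 and 2.03 on array 2. Interferon-stimulated genes had 5 of 20 members higher and none lower (6 higher when adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00141; adjusted p = 0.42 with an estimated correlation). IRF7 rose 1.57-fold, IFI35 1.41-fold and STAT2 1.35-fold. STAT2 lost the call with the authors' log ratios (adjusted p = 0.12) and without background correction (adjusted p = 0.06). The 15 interferon-stimulated genes that did not pass ranged from a log2 ratio of -0.20 (IFIT1) to 0.35 (IFIH1), with ISG15 at 6.150e-04. Members not tested included MX1, OAS1 and RSAD2.

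**Figure D3:**
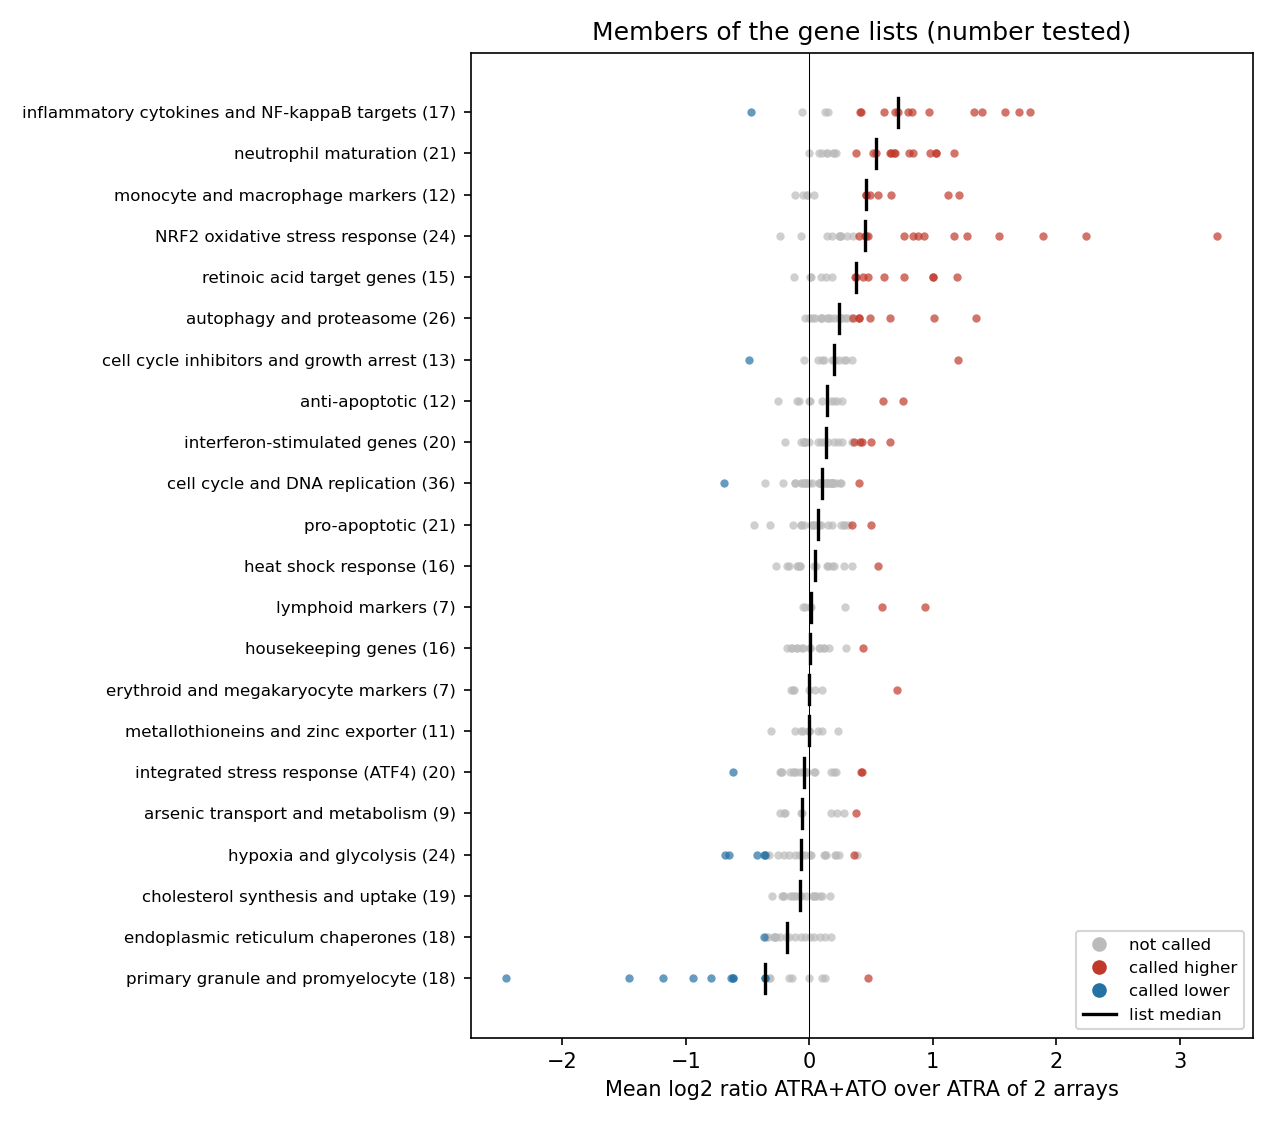
Each row is a gene list fixed before the data were examined, with the number of tested members in brackets; points are members by their mean log2 ratio of 2 arrays, red where called higher and blue where called lower, and the black bar is the list median. The inflammatory list has the highest median, at 0.72, and the primary granule list the lowest, at -0.36.

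Autophagy and proteasome genes were higher in 7 of 26 members and lower in none (10 higher when adjusted over the list alone), with a median log2 ratio of 0.24 (adjusted p = 2.486e-09; adjusted p = 0.36 with an estimated correlation). The members with the largest changes belong to autophagy and the lysosome: the cargo receptor gene SQSTM1 rose 2.55-fold, GABARAPL1 2.01-fold, WIPI1 1.57-fold and LAMP1 1.41-fold. Of 36 cell cycle and DNA replication genes, the proliferation marker gene MKI67 rose 1.33-fold and the replicative helicase gene MCM7 was 1.62-fold lower, with the same counts adjusted over the list alone. The list did not shift by camera (adjusted p = 0.16), but its median of 0.10, which was 0.05 on array 1 and 0.12 on array 2, passed among random lists (adjusted p = 0.00147). MKI67 lost the call with the authors' log ratios (adjusted p = 0.13), without background correction (adjusted p = 0.08) and with a normexp offset of 10 (adjusted p = 0.054). It also lost it with the mean of its probes (adjusted p = 0.07). MYC, a transcription factor of growth, was 1.57-fold lower (log2 -0.65 ± 0.18; adjusted p = 2.807e-04). Cell cycle inhibitors shifted up, with a median of 0.20 over 13 members (adjusted p = 0.00264; adjusted p = 0.42 with an estimated correlation). Of these BTG2 rose 2.31-fold and GADD45B was 1.40-fold lower, and 4 were higher and 1 lower when adjusted over the list alone. CDKN1A, which encodes p21, was not well above background on both arrays in either treatment.

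Anti-apoptotic genes shifted up slightly, with a median of 0.14 over 12 members (adjusted p = 0.03; adjusted p = 0.69 with an estimated correlation). BIRC3 rose 1.69-fold and BCL2A1 1.51-fold, the 2 that passed over all genes and adjusted over the list alone; both are also NF-κB targets. Of 21 pro-apoptotic genes, PMAIP1 rose 1.41-fold and BAX 1.27-fold. BAX lost the call with the authors' log ratios (adjusted p = 0.15), without background correction (adjusted p = 0.09) and with a normexp offset of 10 (adjusted p = 0.09). It also lost it with the mean of its probes (adjusted p = 0.10) and with both other filters on dim probes (adjusted p = 0.06 for each). Adjusted over the list alone, 5 were higher and 2 lower, and the list did not shift (adjusted p = 0.12). CASP8, named after its value was seen, is 1 of the 2 lower, with log2 ratios of 0.12 on array 1 and -1.02 on array 2. Of 24 hypoxia and glycolysis genes, 5 were lower and 1 higher (7 lower and 2 higher when adjusted over the list alone), and the list missed the threshold (adjusted p = 0.05167). PFKFB4 was 1.61-fold lower, the mitophagy receptor gene BNIP3 1.57-fold, ALDOC 1.34-fold and the hexokinase gene HK2 1.29-fold lower. HK2 lost the call with the authors' log ratios (adjusted p = 0.20), without background correction (adjusted p = 0.11) and with a normexp offset of 10 (adjusted p = 0.09). It also lost it with both other filters on dim probes (adjusted p = 0.06 and 0.07). None of 19 cholesterol genes passed, over all genes or adjusted over the list alone; INSIG1 stood at -0.30 ± 0.02 and DHCR7 at -0.22 ± 0.25 (list adjusted p = 0.16).

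Markers of other blood lineages were mostly near 0. Of 7 lymphoid markers, NKG7 rose 1.92-fold while LCK had a log2 ratio of 0.59 and also passed (3 higher when adjusted over the list alone). That list shifted up by camera (adjusted p = 0.01; adjusted p = 0.64 with an estimated correlation), though its median was 0.01. Of 7 erythroid and megakaryocyte markers the haemoglobin gene HBD alone was higher, at 1.64-fold, also when adjusted over the list alone (list adjusted p = 0.69). HBD shares much of its sequence with HBB. Of 16 housekeeping genes 1 was higher and none lower, also when adjusted over the list alone, and the list did not shift (adjusted p = 0.75). Its median was -0.12 on array 1 and 0.15 on array 2, so the arrays differed in sign.

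For genes not well above background in one treatment on both arrays, only a bound on the fold can be given. It rests on mean levels and holds no allowance for error. With ATO, MERTK, a receptor of apoptotic cell uptake, was at least 1.96-fold higher, TOGARAM2 at least 1.85-fold higher and NQO1, a quinone reductase of the NRF2 list, at least 1.57-fold higher. HSD11B2 was at least 1.49-fold lower, TPPP at least 1.39-fold lower and KLHL31 at least 1.28-fold lower, and all 6 passed the limma test. The bound equals the measured ratio for MERTK and nearly so for TOGARAM2 (1.86-fold) and HSD11B2 (1.49-fold). For these genes it is close to the point estimate under the main processing only, in which the offset shrinks the ratios of dim spots. With the authors' log ratios MERTK was 4.39-fold and TOGARAM2 3.91-fold higher, and HSD11B2 was 2.56-fold lower. The KLHL31 call was lost without background correction (adjusted p = 0.09) and without the filter on dim probes (adjusted p = 0.0547).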

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

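Requiring a log2 ratio of 0.58 on each array and leaving out features whose arrays differ by 1 or more were chosen after the data were seen. With median centring in place of loess, 29 features were higher and 3 lower (90.6% higher, against 66.9%), all 32 of them among the 896 calls; 25 and 4 were at least 2-fold on both arrays and the correlation of the arrays was 0.15. Loess removes the intensity-dependent dye curve, which has opposite sign on the turned arrays and otherwise enters the spread. With the authors' log ratios, in the scanner files or the value table, 429 features were higher and 179 lower, 512 of them among the 896 calls, and 98 and 16 were at least 2-fold on both arrays. Without background correction 163 features were lower. The authors' p under 0.01 on both arrays gave 221 higher and 74 lower, and limma called all 295. A limma call with at least 0.58 on each array left 146 higher and 37 lower. Some alternatives gave more calls. Without features whose arrays differ by 1 or more, 694 were higher and 376 lower. With 2 arrays that difference is the spread the test uses. The added calls thus follow from the filter itself and are no support for the main calls. An intensity trend in the variance model gave 698 and 403, and the mean of the probes 646 and 344. Without the filter on dim probes the correlation was 0.37. Camera with an estimated correlation called 0 lists higher and 0 lower, but on 1 residual degree of freedom it cannot decide the question. Medians among 10000 random lists called 10 higher and 2 lower, with the cell cycle list in (adjusted p = 0.00147) and the lymphoid list out (adjusted p = 0.85). The hypoxia list passed with median centring, without the filter on dim probes and with the mean of the probes (adjusted p = 0.02, 0.00767 and 0.04), and the pro-apoptotic list passed under the last 2 of these (adjusted p = 0.04 and 0.04). Apart from the comparisons stated here, the cause was not tested. Leaving out the saturated spots removes nothing, as none is saturated, and is void. Single arrays leave no residual degree of freedom, so limma and camera counts have no value there; at least 2-fold on a single array were 54 to 64 features higher and 11 to 29 lower. The chaperone list median was -0.22 to -0.09, the cell cycle list median 0.05 to 0.12 and the lymphoid list median -0.039 to 0.21 on single arrays. No named gene or list that was called changed direction under another processing setting run; of the 79 named genes called, 59 lost the call with median centring, 11 without background correction, 11 with the authors' log ratios and 7 with a normexp offset of 10. The log2 ratios of the genes that lost the call moved little, by a median of 0.04, under 0.001, 0.005 and 0.002 in that order. The largest move was 0.14, so most calls were lost through a change in spread or threshold. Some genes that kept the call moved more with the authors' log ratios. NQO1 went from 0.88 to 2.96 and HMOX1 from 3.30 to 4.14. Each array holds both treatments, so the test on the ratios is itself paired by array, and no further block could be fitted. Signal limits the rest: 53.9% to 55.8% of spots per channel were well above background.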

Other observations

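All tests of technical explanations here were chosen after the results were seen; the tests of the lysosomal genes and of the MYC targets were written before their members' values were looked at.

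Lysosomal genes not described above were shifted up as a list by camera with a preset correlation, though not with an estimated one. Of 39 measured lysosomal enzymes and membrane proteins, 10 were higher with ATO and none lower, with a median log2 ratio of 0.23 (0.20 on array 1 and 0.25 on array 2; camera p = 6.575e-08 with a preset correlation and p = 0.10 with an estimated one). Among them, the cathepsin gene CTSH had a log2 ratio of 0.60 ± 0.03 (SD, n = 2 arrays) and FUCA1 0.58 ± 0.24. The hypothesis tested was that lysosomal genes shifted as a group, and the median and the preset-correlation test both met it.

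As MYC fell, its textbook targets in ribosome production and nucleotide synthesis were tested as a group. Their median over 30 measured members was -0.26 (-0.30 on array 1 and -0.19 on array 2; camera p = 5.238e-11 with a preset correlation and p = 0.15 with an estimated one), though 2 members alone passed as single genes. These were MRTO4, a ribosome assembly factor, at -0.46 ± 0.26 and ODC1, the first enzyme of polyamine synthesis, at -0.36 ± 0.11. A joint fall does not show that MYC brought it about.

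Probes for HLA class I genes fell as a group, and 6 of 7 tested class I genes were called lower, with a median log2 ratio of -1.04. Brightness-dependent normalization is argued against: with median centring, which has no such step, the class I median was -1.08 and its difference from that of 1020 other features as bright was -1.02, and none of these lay at or under it. All probes reading the same class I transcript is argued against too, since the 12 class I probes spanned 1.30 on the log2 scale, and the extremes lay over 1 apart on each array. Partial cross-hybridisation between class I genes stays open. Of 7 other genes of antigen presentation, chosen after values were seen and not tested as a list, 4 were lower: TAP1 fell by 0.67, TAP2 by 0.45, PSMB9 by 0.38 and PSMB8 by 0.37 on the log2 scale. The other 3 did not pass, with B2M at -0.14 ± 0.01, NLRC5 at -0.09 ± 0.03 and TAPBP at 0.23 ± 0.36 (adjusted p = 0.55, 0.75 and 0.31). A lower expression of class I genes with ATO is a hypothesis that stays open.

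A set of 18 features moved by 1 or more on array 2 and by under 0.3 on array 1, and 0 did the reverse (exact two-sided binomial p = 7.629e-06); 15 of the 18 were lower. A dye effect combined with a treatment effect would give both kinds, and 100% were of the first kind. In 18 of 18 (100%) the Cy5 channel differed between the arrays by more than the Cy3 channel, which is consistent with a shift in the Cy5 channel of array 2. Of their genes, 6 had other tested probes, and 0% of these 7 probes moved the same way by 0.5 or more on array 2 (range -0.20 to 0.39), which argues against a change of the whole transcript for those 6; TRMT2B stood at -2.06 by one probe and 0.39 by the other. For ATM, whose 10 spots had an SD of 0.05 on array 2, or 0.0284 of the difference between arrays, spot noise is excluded as well. For the other 17, with a single spot, noise alike on both arrays is excluded by 17 against 0 genes (exact two-sided binomial p = 1.526e-05), but noise confined to the Cy5 channel of array 2 cannot be told apart from a shift of that channel, because no replicate spot measured them. For 12 genes without another tested probe, a change of the transcript cannot be told apart from it either. The 15 limma calls among the 18 may therefore not reflect ATO.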
